A study of Arabidopsis thaliana with 12 samples.

How the data were processed

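Seeds dissected from siliques of Arabidopsis thaliana were sampled from wild-type Col-0 plants and from plants homozygous for the abi3-6 mutation, at 12 and 16 days after flowering (DAF). Each of the 4 groups held 3 samples, which the labels call biological replicates from separate batches of plants, and each sample was hybridised to its own array, 12 arrays in all. Per the labels' protocols, plants grew under long days, total RNA was purified on columns, and biotin-labelled cRNA was made with a 1-cycle cDNA kit from Affymetrix for 1-colour arrays. Groups were taken from the genotype and age labels.

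The deposited table held 22810 probe sets per array, of which 64 were control probe sets. The submitters' processing notes list GCOS 1.3 and GCRMA 2.0.0, with no role or order given, and other settings were not given in the sources used here. The deposited values were read as log2 expression: no label states the scale, and it was inferred from a range that never reached 0 and array medians between 4.05 and 4.46. Over all probe sets other than controls, array medians were 4.31, 4.27 and 4.34 in wild type at 12 DAF, 4.45, 4.43 and 4.41 in abi3-6 at 12 DAF, 4.05, 4.1 and 4.09 in wild type at 16 DAF, and 4.43, 4.43 and 4.46 in abi3-6 at 16 DAF. Centring by gene was not seen in the values, and whether arrays were centred on a common level stays unknown. GCRMA subtracts a background estimated from probe sequence and so compresses or stretches differences of dim probe sets; no raw intensities were used here.

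Probe sets were named from the platform annotation supplied with the series, which can be old. Of 22746 probe sets other than controls, 13513 had 1 gene, 503 had several and 8730 were unnamed in the table used. Of those with 1 gene, 13436 matched a gene of the TAIR10.1 gene table, which was used for names only. They covered 13286 loci, 144 of them with more than 1 probe set of their own, and such a locus was represented by the probe set with the highest mean over all arrays. No gene was named from a probe set with several genes. ABI3 and many storage protein and light harvesting genes had no probe set paired with them alone in this table, and their levels are not reported here.

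Probe sets were tested where at least 3 of the 12 arrays reached the 40th percentile of all values, 3.16 on the log2 scale. This kept 14873 probe sets and left out 7873 as dim. Of the probe sets kept, 8187 had 1 gene, 344 several and 6342 none. A linear model with a mean for each group was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 8 residual and 5.41 prior degrees of freedom). Contrasts were abi3-6 minus wild type at each age, their mean, their difference (the interaction of genotype and age), and 16 minus 12 DAF within each genotype. Tests were two-sided, and a probe set passed at a Benjamini-Hochberg adjusted p under 0.05 over the probe sets tested. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

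Gene lists of seed storage proteins, oil body proteins, late embryogenesis abundant (LEA) proteins, small heat shock proteins, seed maturation regulators, light harvesting and photosystem proteins, chlorophyll breakdown, fatty acid breakdown and cell division, and markers of seed coat and silique wall, were fixed before the data were examined. So were lists of endosperm markers, fatty acid and triacylglycerol synthesis, abscisic acid, gibberellin, and galactinol and raffinose genes, for which 0 members had a probe set of their own. Of the 42 loci of the light harvesting and photosystem list, 6 had a probe set of their own. Below, "light harvesting genes" is short for these 6, which include photosystem subunits such as PSAE-1 and do not stand for the whole family. A further 15 lists were chosen after the annotation table had been read and before any comparison was computed: oleosins, nuclear genes of photosynthesis, chloroplast-encoded genes, endoplasmic reticulum (ER) body and lectin genes, SWEET transporters, oil breakdown with mitochondrial amino acid breakdown, expansins with xyloglucan endotransglucosylases, vacuolar processing enzymes, flavonoid and seed coat genes, cold and dehydration response, cell division with DNA replication, seed and gibberellin regulators, chaperones, acetyl-CoA supply, and endosperm with seed size genes. Lists with at least 4 measured members were tested with limma's camera at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the lists tested within a contrast, separately for the fixed and the further lists. The same test with an estimated correlation was an alternative.

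Named genes followed a rule fixed before the data were examined. For each genotype contrast they were the 6 largest falls and 6 largest rises among probe sets with 1 gene that passed and whose groups did not overlap. From each list came up to 4 members that passed with the largest changes, with 1 from either direction where both occurred, and every measured maturation regulator. For the interaction the rule took the 4 largest in each direction, and for each age contrast the 4 largest rises, the 4 largest falls and up to 2 members per list. The further lists were read by the same rule. Where all 3 arrays of a group lay under 3.16, that level was used for the group and the difference is given as a lower bound ("at least"). This convention was chosen after the values were seen.

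The procedure was tested on simulated data with the spread of the 14873 probe sets. For the contrast at 12 DAF it recovered 8.96% of 67 changes of 0.5, 68.7% of 67 changes of 1 and 98.5% of 66 changes of 2 on the log2 scale, and 6 of 123 calls (4.88%) were false. In the same simulation 12 of 129 calls (9.3%) were false for age in abi3-6, 4 of 79 (5.06%) for the interaction and 2 of 76 (2.63%) for the mean of both ages, while the comparisons with no simulated change, genotype at 16 DAF and age in wild type, gave 0 calls. Camera gave 7.64e-48 as the p-value of a shifted list, and 3 of 200 lists that were not shifted passed 0.05. Only these few of the 14873 simulated probe sets were changed, whereas 50.8% of probe sets passed at 12 DAF in the data. So large a share lets smaller changes pass the adjusted threshold. The recovered and false shares of the simulation therefore do not carry over to the data. Simulated probe sets were drawn independently of each other, so the simulation does not test the preset correlation for lists whose members move together. Estimated correlations in the data were 0.533 for oleosins and 0.478 for storage proteins, against 0.00377 for LEA proteins. The number of arrays limits the precision, and smaller changes can be missed. The names of the 16 DAF arrays carry a prefix that those of the 12 DAF arrays lack, so age may go with an array batch. The sample titles of wild type at 12 DAF carry a prefix before the replicate number that the other groups lack. What it stands for is not stated in the sources used here, and a separate set of arrays or plants for that group would go with genotype at 12 DAF, with age in wild type and with the interaction. Alternatives covered the filter, array scaling, the model, a replicate block, a fold threshold and each array left out in turn, and their effects are given in the closing section.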

Results

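Transcript levels were measured in developing seeds of Arabidopsis thaliana that were wild type (Col-0) or homozygous for abi3-6, a mutation of ABI3, a B3-domain transcription factor of seed maturation. Seeds were taken at 12 and 16 days after flowering (DAF), with 3 arrays for each of the 4 groups and each array from a separate batch of plants. No probe set was paired with ABI3 alone in the annotation used, so the level of the mutated gene itself, which would check the labels, is not reported here. Arrays of a group correlated with r between 0.983 and 0.994 across probe sets. Mean correlations between the genotypes were 0.882 at 12 DAF and 0.747 at 16 DAF. Between 13507 and 13931 probe sets per array lay above the limit of 3.16 log2 units used to set aside dim signals. The number of arrays limits the precision of every value below.

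**Figure D1:**
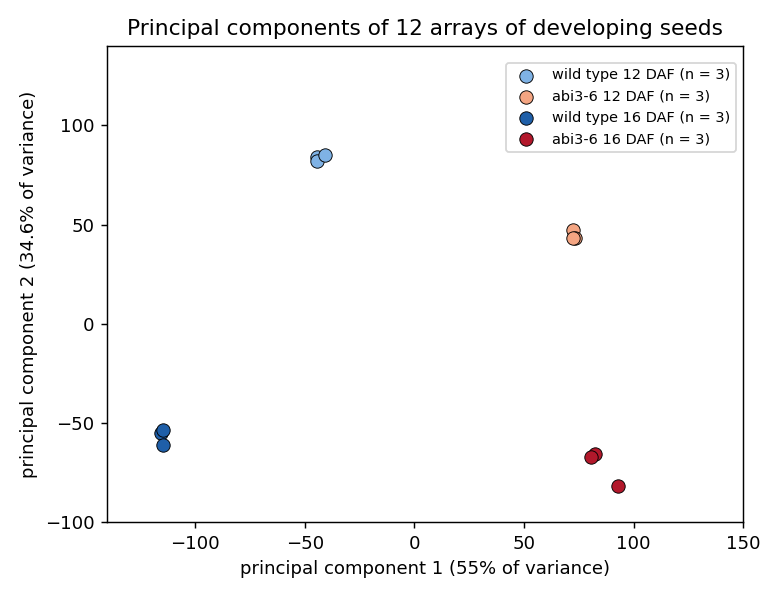
Principal components of the 12 arrays over the tested probe sets, component 1 (55% of the variance) on the x axis and component 2 (34.6%) on the y axis. Each point is an array, and the 3 arrays of each group lie together and apart from the other groups.

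The first comparison asked which transcripts differed between abi3-6 and wild-type seeds at 12 DAF. In the mutant 16 of 18 late embryogenesis abundant genes and all 4 measured oleosins were lower. Higher were 6 of 6 measured light harvesting and photosystem genes, 23 of 29 nuclear photosynthesis genes and 34 of 69 chloroplast-encoded genes. Of the ER body list 6 of 8 genes were higher, while BGLU19 fell. The list calls of oleosins, chloroplast-encoded genes and ER body genes were lost with an estimated correlation between members (limma camera, Benjamini-Hochberg adjusted p = 0.292, 0.349 and 0.227 with an estimated correlation), and the others held. AT5G45690 fell from 13.59 ± 0.06 to 2.83 ± 0.21 log2 units (SD, n = 3), at least 1377-fold. The oleosin AT2G25890, of a family that coats oil bodies, fell from 12.51 ± 0.14 to 2.23 ± 0.18 (SD, n = 3), at least 652-fold. PYK10, the main beta-glucosidase of ER bodies, rose from 2.51 ± 0.04 to 10.32 ± 0.12 (SD, n = 3), at least 143-fold.

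The other large falls at 12 DAF were those of AT3G60730, a pectin methylesterase family gene (at least 619-fold), AT3G56350, a superoxide dismutase family gene (log2 fold change -9.44 ± 0.31 SE), AT5G07330 (-9.01 ± 0.16) and BGLU19, a beta-glucosidase (-9.01 ± 0.28). Large rises were those of AT1G47400 (8.64 ± 0.20 SE), NAI2, an ER body component (7.72 ± 0.25), AT3G28220, a TRAF-like gene (7.04 ± 0.16), ZW9 (6.92 ± 0.24) and AT1G66180, an aspartyl protease family gene (at least 59.1-fold). Of the 3 wild-type arrays, 2 lay above the dim limit for AT1G47400 and ZW9, and 1 for NAI2. For each of these 12 genes all 3 mutant arrays lay on the same side of all 3 wild-type arrays, as the rule for naming required. Their Benjamini-Hochberg adjusted p in limma ran from 2.3e-15 to 2.33e-08.

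Late embryogenesis abundant (LEA) proteins, which accumulate as seeds acquire desiccation tolerance, fell as a group at 12 DAF. Of 18 measured, 16 were lower, 0 higher and 2 did not pass, and 16 passed when adjusted over the list alone. AT3G53040 fell by 7.78 ± 0.21 (SE, 2 of 3 mutant arrays above the dim limit), AT1G72100 at least 77.2-fold, AT3G15670 by 5.85 ± 0.25 and AtLEA4-1 by 5.01 ± 0.25 log2 units. The median change was -3.76, or -3.30 with 4 members at their bound (limma camera, Benjamini-Hochberg adjusted p = 3.49e-11, and adjusted p = 0.000383 with an estimated correlation).

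Of 5 measured seed storage proteins, 3 were lower at 12 DAF, 0 higher and 2 did not pass, and 3 passed when adjusted over the list alone. The cruciferin-like AT1G03890 fell by 1.99 ± 0.44 (SE), AT2G18540 by 1.94 ± 0.27 and AT2G28490 by 0.97 ± 0.22 log2 units. The list as a whole did not pass (median -0.97, limma camera, Benjamini-Hochberg adjusted p = 0.104). All 3 measured oil body proteins were lower, and 3 passed when adjusted over the list alone: AT3G18570 had a log2 fold change of -2.30 ± 0.41 (SE), OLEO3 of -2.29 ± 0.32 and AT3G01570 of -0.98 ± 0.28. With AT2G25890 they made up the 4 measured oleosins, all lower, with a median of -2.30 (limma camera, Benjamini-Hochberg adjusted p = 0.00276, but adjusted p = 0.292 with an estimated correlation).

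Small heat shock proteins, chaperones that bind unfolding proteins, fell for 3 of 6 members, with 0 higher and 3 that did not pass, and 3 passed when adjusted over the list alone. AT1G53540 was at least 2.90-fold lower, AT5G37670 fell by 2.08 ± 0.23 (SE) and AT1G54050 by 1.99 ± 0.20 log2 units. The median was -1.14 (limma camera, Benjamini-Hochberg adjusted p = 0.0346, but adjusted p = 0.246 with an estimated correlation). It was -0.77 with 2 members at their bound and 1, under the dim limit in both genotypes, set to no difference. The call was also lost with array weights (adjusted p = 0.0628), with no filter (0.0687) and without wild type 12 DAF replicate 2 (0.0663, median -1.12), in a range of 0.00695 to 0.246 over the alternatives.

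All 6 measured light harvesting and photosystem genes were higher in abi3-6 at 12 DAF, and all 6 passed when adjusted over the list alone. LHCB4.1, an antenna protein of photosystem II, rose by 3.58 ± 0.17 (SE), PSBW by 3.21 ± 0.16, PSAE-1, a subunit of photosystem I, by 2.85 ± 0.15 and PSAN by 2.70 ± 0.14 log2 units. The median was 2.77 (limma camera, Benjamini-Hochberg adjusted p = 2.17e-06, and adjusted p = 0.00211 with an estimated correlation). Among 29 nuclear genes of photosynthesis and chlorophyll synthesis 23 were higher, 0 lower and 6 did not pass. PORB, which reduces protochlorophyllide, rose by 5.46 ± 0.30, ATPC1 by 4.95 ± 0.15, CaS by 3.66 ± 0.18 and CHLM by 3.41 ± 0.21 (median 1.58, limma camera, Benjamini-Hochberg adjusted p = 3.96e-09, and adjusted p = 0.045 with an estimated correlation). Of 69 chloroplast-encoded genes 34 were higher, 0 lower and 35 did not pass. Among them rps2 rose by 2.24 ± 0.25, rpoC1 by 1.94 ± 0.24, atpH by 1.75 ± 0.19 and rpoC2 by 1.62 ± 0.21. Their median was 0.71 (limma camera, Benjamini-Hochberg adjusted p = 4.61e-05, but adjusted p = 0.349 with an estimated correlation), and cDNA kits that prime on poly(A) tails sample such transcripts poorly.

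ER body and lectin genes moved strongly, 6 of 8 higher, 1 lower and 1 that did not pass. The lectin JAL34 was at least 20.1-fold higher beside PYK10 and NAI2, and BGLU19 was the member that fell. The median was 2.65, or 2.33 with 5 members at their bound (limma camera, Benjamini-Hochberg adjusted p = 0.013, but adjusted p = 0.227 with an estimated correlation). SWEET sugar transporters were lower for 5 of 6 and higher for 1: SWEET6 fell at least 7.66-fold, SWEET2 at least 2.28-fold and SWEET11 by 1.41 ± 0.16 (SE), and SWEET1 rose by 2.46 ± 0.19. That list's median was -1.37 (limma camera, Benjamini-Hochberg adjusted p = 0.0476, but adjusted p = 0.349 with an estimated correlation). A list of oil and amino acid breakdown genes rose for 7 of 11, with 0 lower and 4 that did not pass. Its oil breakdown members, the glyoxylate cycle enzyme ICL (1.47 ± 0.14), AIM1 of peroxisomal fatty acid oxidation (1.31 ± 0.16) and the lipase genes SDP1 and SDP1-LIKE, all rose. Of its other 7 members, which act in mitochondrial amino acid breakdown and the electron transfer it feeds, 3 rose, among them MCCB of leucine breakdown by 2.18 ± 0.18. The median was 0.77 (limma camera, Benjamini-Hochberg adjusted p = 0.0476, but adjusted p = 0.437 with an estimated correlation). Both last calls held in 8 of 16 alternatives. With no filter the SWEET median was -0.0645. Leaving out abi3-6 replicate 1 or 2 or wild type replicate 1 ended both calls, with medians from -1.40 to -1.34 for SWEET and from 0.690 to 0.757 for oil and amino acid breakdown, and leaving out wild type replicate 3 ended the latter (0.671).

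Of the maturation regulators only EEL and BZIP53, both bZIP factors, were measured. EEL fell by 1.29 ± 0.23 (SE), and BZIP53 differed by -0.24 ± 0.18, which did not pass. The 3 members of the fixed fatty acid breakdown list, ICL, AIM1 and the lipase SDP1 (0.86 ± 0.19), all rose. The remaining fixed lists had few members. The chlorophyll breakdown gene NOL rose by 0.50 ± 0.20, the cell division kinase AUR2 by 0.41 ± 0.14 and the seed coat protease ARA12 by 0.52 ± 0.15. The seed coat gene BAN differed by -0.10 and did not pass, and the silique wall marker ALC fell by 1.14 ± 0.29, with 1 of 3 mutant arrays above the dim limit. Counts adjusted over the list alone were the same for these small lists. The call of ARA12 was lost after quantile normalization (0.36) and without abi3-6 replicate 1 (0.40). That of AUR2 was lost without abi3-6 replicate 2 (0.40) or 3 (0.41) or wild type replicate 3 (0.32). That of NOL was lost after both scalings, with no filter and without any array but wild type replicate 2 (0.39 to 0.57).

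Across all probe sets at 12 DAF, 7560 of 14873 passed (limma, Benjamini-Hochberg), 4030 higher and 3530 lower in abi3-6. The majority turned with the scaling, to 3715 higher and 3989 lower after centring and 3642 and 3998 after quantile normalization, and with no filter on dim probe sets, to 3973 and 4192. A change of at least 2-fold was found for 1886 higher and 1383 lower, of which 1556 were unnamed, and a change of at least 8-fold for 247 higher and 144 lower. The difference between actin 3′ and 5′ control probe sets moved with genotype, at -0.37 ± 0.17 in wild type and 0.37 ± 0.09 in abi3-6 (SD, n = 3, log2), beside the gene groups above.

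At 16 DAF the same question was asked of seeds nearer to maturity. AT5G45690 was at least 1504-fold lower, and the oleosin AT2G25890 went from 13.10 ± 0.03 to 2.04 ± 0.03 (SD, n = 3), at least 978-fold. BGLU19 had a log2 fold change of -10.90 ± 0.28 (SE, 2 of 3 mutant arrays above the dim limit) and the LEA gene AT3G53040 of -10.34 ± 0.21 (1 of 3), and the LEA gene AT3G22490 was at least 586-fold lower; lower bounds give no order among these falls. PYK10 reached 13.17 ± 0.19 in the mutant against 3.43 ± 1.54 in wild type (SD, n = 3), where 1 of 3 arrays lay above the dim limit. CP1, a cysteine protease, rose by 8.19 ± 0.40 (SE).

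AT3G15280 also fell at 16 DAF, at least 551-fold. Rises included NAI2 (at least 653.5-fold), the lectin JAL33 (at least 288.5-fold), AT1G74470, the geranylgeranyl reductase of chlorophyll synthesis (8.33 ± 0.23 SE), and ZW9 (8.20 ± 0.24). For these last 2 genes, 2 and 1 of 3 wild-type arrays lay above the dim limit. Benjamini-Hochberg adjusted p of these 12 genes in limma ran from 7.18e-16 to 8.86e-10, again with 3 mutant arrays on the same side of 3 wild-type arrays for each.

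Of 18 LEA genes 17 were lower at 16 DAF and 1 was higher, and the same numbers passed when adjusted over the list alone. AT4G36600 fell by 9.43 ± 0.18 (SE, 2 of 3 mutant arrays above the dim limit), and AT2G03850 was the member that rose, at least 5.75-fold. The median was -6.32 (limma camera, Benjamini-Hochberg adjusted p = 5.39e-10, and adjusted p = 0.000587 with an estimated correlation). All 5 storage protein genes were lower, and 5 passed when adjusted over the list alone. AT1G03890 fell by 5.08 ± 0.44, AT2G28490 by 3.56 ± 0.22, AT4G36700 by 2.63 ± 0.42 and AT2G18540 by 2.19 ± 0.27. The median was -2.63 (limma camera, Benjamini-Hochberg adjusted p = 0.00324, but adjusted p = 0.117 with an estimated correlation). The 3 oil body proteins fell as well, AT3G18570 by 7.49 ± 0.41, OLEO3 by 5.71 ± 0.32 and AT3G01570 by 3.86 ± 0.28, and 3 passed when adjusted over the list alone. For AT3G18570 2 of 3 mutant arrays lay above the dim limit. The 4 oleosins had a median of -6.60 (limma camera, Benjamini-Hochberg adjusted p = 0.00102, but adjusted p = 0.226 with an estimated correlation).

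Among small heat shock proteins 5 of 6 were lower at 16 DAF and 1 was higher, also when adjusted over the list alone. AT1G53540 was at least 124-fold lower, AT1G54050 fell by 6.11 ± 0.20 (SE) and AT5G37670 by 4.14 ± 0.23, while AT4G21870 rose by 1.33 ± 0.27, with 1 of 3 wild-type arrays above the dim limit. The median was -4.14, or -3.77 with 2 members at their bound (limma camera, Benjamini-Hochberg adjusted p = 0.00119, but adjusted p = 0.0829 with an estimated correlation). Both measured regulators were lower, EEL with a change of -1.60 ± 0.23 and BZIP53 of -0.85 ± 0.18, and both passed when adjusted over the list alone.

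All 6 light harvesting and photosystem genes rose at 16 DAF, and all 6 passed when adjusted over the list alone. PSAE-1 was at 11 ± 0.28 in abi3-6 and 5.03 ± 0.13 in wild type (SD, n = 3), PSBY rose by 5.90 ± 0.20 (SE, 2 of 3 wild-type arrays above the dim limit), PSBW by 4.88 ± 0.16 and PSAN at least 26.8-fold. The median was 4.98, or 4.81 with 1 member at its bound (limma camera, Benjamini-Hochberg adjusted p = 2.28e-05, and adjusted p = 0.00401 with an estimated correlation). Of the 29 nuclear photosynthesis genes 24 were higher, 2 lower and 3 did not pass. ATPC1 rose at least 138-fold, PORB at least 128-fold and PRK, a Calvin cycle kinase, at least 30.8-fold, and ATPC2 fell by 0.82 ± 0.17. The median was 1.97 (limma camera, Benjamini-Hochberg adjusted p = 1.48e-06, but adjusted p = 0.114 with an estimated correlation). Of 69 chloroplast-encoded genes 46 were higher, 0 lower and 23 did not pass. Among them rps4 rose by 2.38 ± 0.32, atpF by 2.31 ± 0.37 and petA by 1.95 ± 0.18 (median 0.95, limma camera, Benjamini-Hochberg adjusted p = 0.000492, but adjusted p = 0.316 with an estimated correlation).

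ER body and lectin genes were higher for 7 of 8 at 16 DAF, with BGLU19 lower. The median was 5.68, or 5.41 with 3 members at their bound (limma camera, Benjamini-Hochberg adjusted p = 0.00244, but adjusted p = 0.116 with an estimated correlation). SWEET transporters were lower for 5 of 6, with 0 higher and 1 that did not pass. SWEET6 fell at least 109-fold, SWEET11 by 2.05 ± 0.16 (SE), SWEET7 fell by 1.79 ± 0.21 and SWEET10 by 1.76 ± 0.26 (median -1.78, limma camera, Benjamini-Hochberg adjusted p = 0.017, but adjusted p = 0.227 with an estimated correlation). That call was lost with no filter on dim probe sets (adjusted p = 0.0629, in a range of 0.00725 to 0.227 over the alternatives), where the list's median was -0.12. Oil and amino acid breakdown genes split, 5 higher and 5 lower with 1 that did not pass (median 0.00, limma camera, Benjamini-Hochberg adjusted p = 0.957). Among the oil breakdown members ICL and SDP1-LIKE were higher and SDP1 and AIM1 lower. Of the mitochondrial members, ETFALPHA of electron transfer rose by 2.1 ± 0.21 and MCCB by 2.17 ± 0.18, and ETFQO, also of electron transfer, fell by 1.73 ± 0.15 and MCCA of leucine breakdown by 1.37 ± 0.18.

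Expansins and xyloglucan endotransglucosylases, which loosen cell walls, were higher for 6 of 9 at 16 DAF, with 2 lower and 1 that did not pass. EXPA9 rose at least 29.4-fold, XTH19 by 5.30 ± 0.26 (SE) and EXPA20 by 4.88 ± 0.17 (2 of 3 wild-type arrays above the dim limit), and EXLA1 fell by 1.84 ± 0.30. The list did not pass (median 1.82, limma camera, Benjamini-Hochberg adjusted p = 0.0569), though it did after both scalings and without abi3-6 16 DAF replicate 1 or 2 (2.003 and 2.004), and its median was -0.0583 with no filter. It did not pass at 12 DAF either, with 3 higher, 5 lower and 1 that did not pass (median -0.56, adjusted p = 0.575). In the small lists NOL rose by 1.05 ± 0.20, ARA12 by 1.45 ± 0.15 and ALC by 1.34 ± 0.29 (1 of 3 wild-type arrays above the dim limit), AUR2 fell by 0.48 ± 0.14, and BAN lay under the dim limit in all arrays of both genotypes, so that no difference is given. ICL rose by 0.94 ± 0.14, while SDP1 fell by 0.67 ± 0.19 and AIM1 by 0.51 ± 0.16, and counts adjusted over the list alone were the same for the small lists. The call of AIM1 was lost without wild type 16 DAF replicate 3 (-0.36, limma, Benjamini-Hochberg adjusted p = 0.071).

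**Figure D2:**
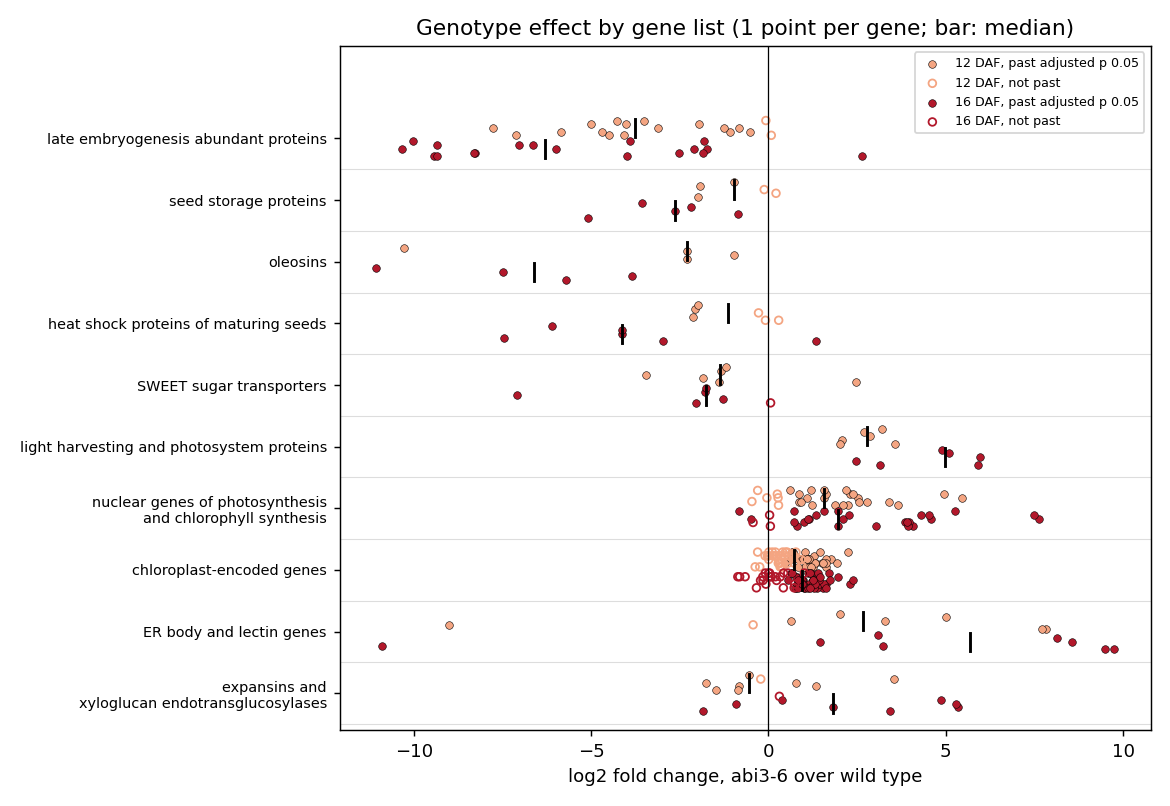
Log2 fold change of abi3-6 against wild type (x axis) for the measured members of 10 gene lists (y axis) at 12 and 16 DAF. Each point is a gene, filled where its adjusted p was under 0.05, and the bar is the list's median. Light harvesting and photosystem genes lie to the right of 0 and most LEA genes to the left of 0 at both ages.

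In total 10439 of 14873 probe sets passed at 16 DAF (limma, Benjamini-Hochberg), 5288 higher and 5151 lower in abi3-6. With no filter on dim probe sets 14477 passed, 5399 higher and 9078 lower. Changes of at least 2-fold were 3373 higher and 2556 lower, 2717 of these unnamed, and changes of at least 8-fold 695 higher and 359 lower. Aligning the arrays on their medians over the tested probe sets moved this contrast by 0.136 log2 units, and the share of higher calls was then 44.6% against 50.7%. The median of the light harvesting list was 4.84 on that scale. Actin 3′ minus 5′ signal was -0.21 ± 0.02 in wild type and 0.37 ± 0.03 in abi3-6 (SD, n = 3, log2) beside the gene groups above.

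**Figure D3:**
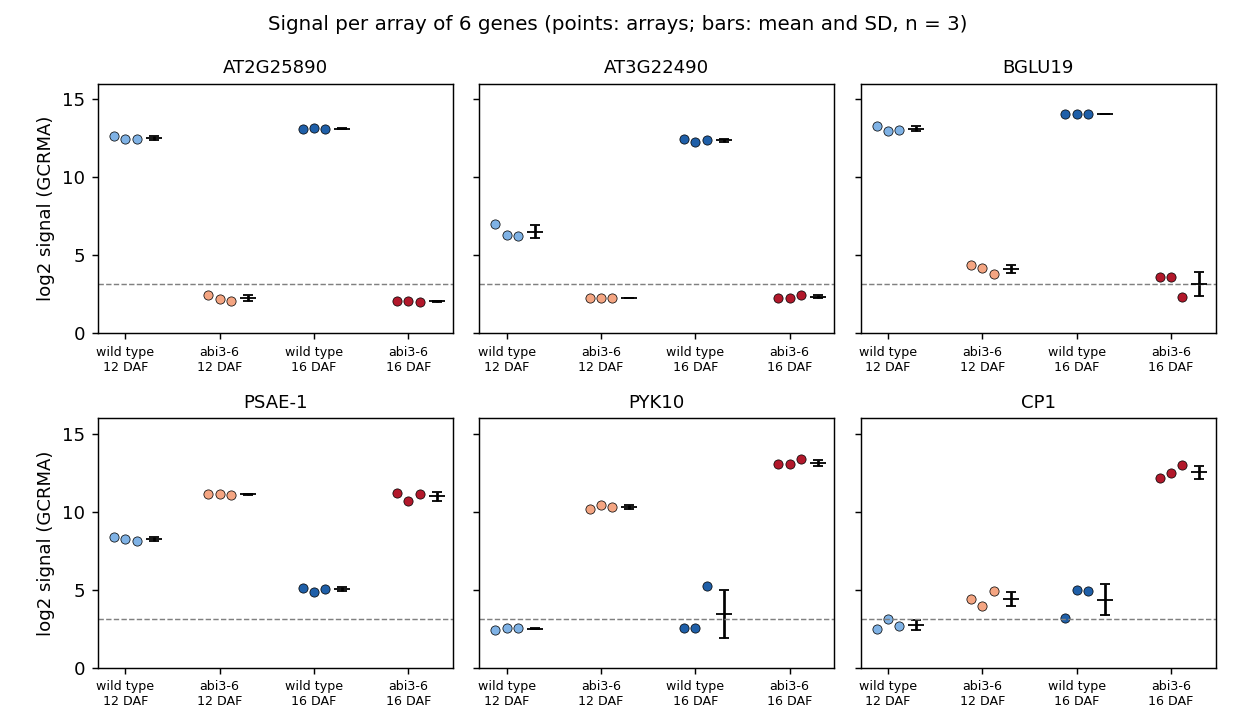
Log2 expression (y axis) of AT2G25890, AT3G22490, BGLU19, PSAE-1, PYK10 and CP1 in each array by group (x axis), with mean and SD of 3 arrays, and the dim limit of 3.16 as a dashed line. AT2G25890 lies under the limit in all abi3-6 arrays, and PSAE-1 lies higher in abi3-6 than in wild type at both ages.

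The genotype contrasts at both ages were then set side by side; they share no array. Of 6157 probe sets that passed at both ages, 5805 (94.3%) moved the same way, 3125 higher and 2680 lower, where 1433 and 1223 would be shared by independent lists. The majority was lower after centring (2817 higher and 3167 lower), after quantile normalization (2815 and 3192) and with no filter (3052 and 3232). The other 352 went opposite ways. Across probe sets, which are not independent replicates, the log2 fold changes correlated with r = 0.768 and rho = 0.721. For the mean of both ages 11058 probe sets passed (limma, Benjamini-Hochberg), 5584 higher and 5474 lower. The split was 5047 and 6204 after centring, 5101 and 6160 after quantile normalization, and 5721 and 10541 with no filter on dim probe sets. LEA genes were lower for 17 of 18 in that mean and higher for 1 (median -4.43), storage proteins for 5 of 5 (-2.06), and light harvesting genes were higher for 6 of 6 (3.92).

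Whether the genotype difference itself changed with age was tested as an interaction. LEA genes differed more at 16 DAF, with 14 of 18 more negative and 1 more positive (median interaction -2.15, limma camera, Benjamini-Hochberg adjusted p = 1.34e-07, and adjusted p = 0.00163 with an estimated correlation). Small heat shock proteins had a median of -3.56 (limma camera, Benjamini-Hochberg adjusted p = 0.000129, and adjusted p = 0.0418 with an estimated correlation), and light harvesting genes 2.03 (adjusted p = 0.00116, and adjusted p = 0.0184 with an estimated correlation). With groups under the dim limit set to it these medians were -2.17, -3.33 and 1.86. Storage proteins had a median of -2.51 (limma camera, Benjamini-Hochberg adjusted p = 0.00474, but adjusted p = 0.13 with an estimated correlation). The interaction was also negative for AT2G34740, a protein phosphatase 2C family gene, and AT3G22490. Both lay under the dim limit in all abi3-6 arrays at both ages, so the size of their interaction was not measured. CP1 had a positive interaction, at most 6.93 with wild type at 12 DAF, where all arrays were dim, set to the limit. The interaction passed for 5971 probe sets (40.1% of those tested, limma, Benjamini-Hochberg), 3155 positive and 2816 negative (2886 and 3184 after centring). Of the 122 genes named in the genotype contrasts it passed for 86. Nearly all of these genes were picked for large changes in the same data, so the 2 shares are not comparable.

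Age was compared within each genotype, from 12 to 16 DAF; age may go with an array batch here, and the 2 cannot be told apart. The sample titles set wild type at 12 DAF apart by a prefix, so a separate set of that group, which also enters the genotype contrast at 12 DAF, stays open. In wild type, LEA genes rose for 14 of 18 members, with 0 lower and 4 that did not pass, and 14 passed when adjusted over the list alone. M17 rose by 6.45 ± 0.43 (SE) and AT3G22490 by 5.85 ± 0.17 (list median 2.24, limma camera, Benjamini-Hochberg adjusted p = 1.37e-06, and adjusted p = 0.00275 with an estimated correlation). Small heat shock proteins rose for 5 of 6, also when adjusted over the list alone, AT1G53540 by 5.42 ± 0.28 and ATHSP22.0 at least 10.6-fold (median 3.81, limma camera, Benjamini-Hochberg adjusted p = 0.000462, but adjusted p = 0.0574 with an estimated correlation). Light harvesting genes fell for 5 of 6, also when adjusted over the list alone, PSBY by 5.35 ± 0.20 (2 of 3 arrays at 16 DAF above the dim limit) and PSAN at least 7.58-fold (median -2.68, limma camera, Benjamini-Hochberg adjusted p = 0.000835, and adjusted p = 0.016 with an estimated correlation). Storage proteins were lower for 1 of 5, also when adjusted over the list alone, and did not pass as a list (median -0.39, limma camera, Benjamini-Hochberg adjusted p = 0.446).

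Large single-gene changes with age in wild type were falls of FACT, a caffeoyl-CoA transferase (-7.58 ± 0.14 SE), the peroxidase AT4G25980 (-7.10 ± 0.15), AT2G18360 (at least 65.2-fold) and the germin-like AT3G04200 (at least 52.6-fold). Large rises were those of AT2G34740 (7.33 ± 0.27), the dynein light chain gene AT3G16120 (6.75 ± 0.17) and the chitinase family gene AT2G43580 (6.58 ± 0.32). At their dim age 1 of 3 arrays of FACT, AT3G16120 and AT2G43580 and 2 of AT2G34740 lay above the dim limit. SWEET11 fell by 4.53 ± 0.16 and SPT, a bHLH factor, fell by 4.19 ± 0.18, and SWEET6 rose by 3.83 ± 0.23. In all 9281 probe sets passed in wild type (limma, Benjamini-Hochberg), 4762 higher and 4519 lower at 16 DAF. Falls were the majority among changes of at least 2-fold (2246 higher and 2819 lower) and of at least 8-fold (226 and 459), and the split was 5417 and 4158 after centring.

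In abi3-6 seeds LEA genes split over the same interval, 7 higher, 6 lower and 5 that did not pass, also when adjusted over the list alone (median 0.05, limma camera, Benjamini-Hochberg adjusted p = 0.665). M10 rose by 3.48 ± 0.27 (SE) and the gene named LEA fell by 2.16 ± 0.32. Storage proteins were lower for 4 of 5, also when adjusted over the list alone. AT4G36700 fell by 4.19 ± 0.42 and AT1G03890 fell by 3.72 ± 0.44 (median -2.98, limma camera, Benjamini-Hochberg adjusted p = 0.00382, but adjusted p = 0.168 with an estimated correlation). Of the 4 oleosins 3 fell, where OLEO3 fell by 6.39 ± 0.32 and AT3G18570 fell by 5.39 ± 0.41 (median -4.35, limma camera, Benjamini-Hochberg adjusted p = 0.00589, but adjusted p = 0.437 with an estimated correlation). ER body and lectin genes rose for 6 of 8 with 1 lower, JAL33 by 5.35 ± 0.14 (median 2.26, limma camera, Benjamini-Hochberg adjusted p = 0.00589, but adjusted p = 0.22 with an estimated correlation). Small heat shock proteins were higher for 2 of 6 and lower for 0, and light harvesting genes lower for 4 of 6 and higher for 0, both also when adjusted over the list alone. Neither list passed (medians 0.19 and -0.50, limma camera, Benjamini-Hochberg adjusted p = 0.372 and 0.0607).

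Among large rises in abi3-6 were those of CP1 (8.14 ± 0.40 SE), AT5G26260, a TRAF-like gene (at least 95.5-fold), and the cysteine protease AT1G29090 (at least 58.1-fold). FACT fell at least 138-fold, the lipid-transfer protein gene AT2G18370 at least 147-fold, AT2G34700 by 7.13 ± 0.59 and AT3G58550 by 7.07 ± 0.29. In all 7522 probe sets passed (limma, Benjamini-Hochberg), 4028 higher and 3494 lower at 16 DAF. Here too falls were the majority among changes of at least 2-fold (1468 higher and 1760 lower) and of at least 8-fold (112 and 260). Of the 4762 that rose in wild type 2394 also rose in abi3-6, 230 fell and 2138 did not pass, and the interaction passed for 2244. Of the 4519 that fell in wild type 2478 also fell, 349 rose and 1692 did not pass, and the interaction passed for 2485. Independent lists would share 1290 and 1062.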

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

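The splits of the arrays and the tests of explanations in this part were chosen only after the results were seen. The interaction tests of probe sets and of the storage protein, LEA, small heat shock and light harvesting lists were planned, and the oleosin, SWEET, nuclear photosynthesis, expansin and ER body lists were chosen after the annotation had been read.

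The genotype difference changed between 12 and 16 DAF for 5971 probe sets. Storage proteins (median interaction -2.51), LEA proteins (-2.15), small heat shock proteins (-3.56), oleosins (-3.15) and SWEET transporters (-0.597) were more negative at 16 DAF. Light harvesting genes (2.03), nuclear photosynthesis genes (0.454), expansins (0.866) and ER body genes (1.84) were more positive. With an estimated correlation the list calls that held were those of LEA proteins, small heat shock proteins and light harvesting genes; the others gave limma camera, Benjamini-Hochberg adjusted p = 0.13 with an estimated correlation for storage proteins, 0.295 for oleosins, 0.36 for both SWEET transporters and nuclear photosynthesis genes, and 0.152 for both expansins and ER body genes. With no filter the SWEET median was -0.0719 and the expansin median 0.0602, both without a call, and the SWEET call held in 11 of 21 alternatives. With groups under the dim limit set to it, medians were -2.17 for LEA proteins, -3.33 for small heat shock proteins, 1.86 for light harvesting genes, 0.556 for nuclear photosynthesis genes and 2.1 for ER body genes, and those of the other lists did not move. The small heat shock gene AT1G52560 had an interaction of -6.52, with all arrays above the dim limit. Fitted values for other single genes include groups under that limit and so are no exact sizes: AT2G34740 (-7.30), AT2G43580 (-6.31) and AT3G22490 (-5.77), dim in abi3-6 at both ages, AT5G26260 (6.97) and AT1G29090 (6.31), dim in all groups but abi3-6 at 16 DAF, CP1 (6.53), dim in wild type at 12 DAF, and the expansin EXPA9 (6.16, at least 5.71), dim in wild type at 16 DAF. Named genes whose change passed at both ages in opposite directions were ALC (-1.14 at 12 DAF, 1.34 at 16 DAF, interaction 2.48), COR47 (-1.26, 3.42 and 4.68), DELTA-VPE (-1.34, 2.38 and 3.72), DFR (-1.36, 2.73 and 4.09), AIM1 (1.31, -0.51 and -1.82), SDP1 (0.86, -0.67 and -1.53) and AUR2 (0.41, -0.48 and -0.89).

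Other splits of the arrays were refitted. For contrasts of 3 against 3 arrays there are 10 splits, too few for a share under 0.05: 7560 probe sets passed in the real split at 12 DAF, 10439 at 16 DAF, 9281 for age in wild type and 7522 for age in abi3-6, and the highest other split gave 0 in each. For the genotype effect over both ages 1 of 100 splits, the real one, gave as many as 11058, the highest other giving 7352. That share is the smallest these splits can give, and it argues against chance without excluding it. For the interaction 4 of 100 splits gave as many as 5971, the highest other 11058. These splits exchange genotypes within ages, so that the mean genotype effect itself gives interaction calls in them, and they do not test chance for the interaction.

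The 6 measured light harvesting and photosystem genes were all higher in abi3-6 seeds at both ages. So were 23 of 29 nuclear photosynthesis genes at 12 DAF and 24 at 16 DAF, where 2 were lower and 3 did not pass. The call of the nuclear list at 16 DAF was lost with an estimated correlation (limma camera, Benjamini-Hochberg adjusted p = 0.114 with an estimated correlation). Those of chloroplast-encoded genes at 12 and 16 DAF were lost with it too (0.349 and 0.316). A delay of the mutant at 16 DAF to a wild-type stage from 12 DAF on is argued against for the 6 light harvesting genes. With age 5 of them fell in wild type and 0 rose. Yet their smallest rise in the mutant at 12 DAF was 2.03, and their largest change with age there -1.475. All 35 nuclear genes lay above wild type at 12 DAF by a median of 1.82 (quartiles 1.02 and 3.03, 28 called higher and 2 lower). The 29 of the nuclear list mark no stage, since 11 rose and 10 fell with age in wild type. An array batch that goes with age, or a separate set of wild type at 12 DAF, would enter these values. A stage before 12 DAF stays open. Scaling of the arrays by the authors is argued against as the whole cause. The light harvesting median at 16 DAF was 4.87 after quantile normalization and 4.84 after centring. The shift of array medians over the tested probe sets was 0.136. Over all probe sets other than controls the array medians at 16 DAF lay further apart, from 4.05 in wild type to 4.46 in abi3-6. Silique wall tissue in the mutant samples cannot be told apart, because the only measured marker, ALC, was near the dim limit of 3.16 (group means 2.90 to 4.25) and went from -1.14 to 1.34. A biological effect of losing ABI3 on these genes remains a hypothesis beside it.

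Genotype differences were larger at 16 than at 12 DAF: the median absolute log2 fold change was 0.766 against 0.463, and 75.2% of probe sets that passed at both ages in the same direction changed more at 16 DAF. A scale factor between the array sets of the ages would give a slope over 1 of the changes at 16 on those at 12 DAF. That slope was 1.28 through these probe sets. As the whole cause it is argued against, since it would leave the correlation between genotypes unchanged. That was 0.882 at 12 and 0.747 at 16 DAF, with at least 0.98 within groups. Nor would it turn or shrink changes, yet 352 probe sets passed in opposite directions. Among the interaction calls of the others 298 were smaller and 2190 larger at 16 DAF. As a part of the cause it cannot be told apart from a change with age. The least typical array, abi3-6 16 DAF replicate 3, is argued against, since the medians without it were 0.752 and 0.463, and 75.9% of such probe sets changed more at 16 DAF. A longer time without ABI3 may add to the difference and was not tested, and an array batch that goes with age cannot be told apart from age.

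Actin control probe sets, outside the comparisons, showed a 3′ minus 5′ difference that was higher in abi3-6 by 0.655 ± 0.0561 (SE, log2) over both ages (exact permutation p = 0.005 over 400 splits within ages, 0.015 after Benjamini-Hochberg over 3 transcripts). Degradation acting alike on the control transcripts is argued against, since the difference was 0.0335 ± 0.0669 for ubiquitin (exact permutation p = 0.655) and 0.128 ± 0.15 for GAPDH (exact permutation p = 0.48, adjusted 0.655). A change specific to actin transcripts could underlie it and was not tested.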

How the results depend on the processing

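Alternatives were planned before the data were examined, except that those for the further gene lists, the lower bounds on folds and the size of differences without 1 array were chosen after the annotation or the values had been seen; log2(value + 16) was planned for linear values and not run, since the values were read as log2 from their range, a scale that no label states. No list median or named gene that passed turned its direction in any alternative run, though the majority of higher or lower calls turned in some, as given beside those counts above and for Welch's test below. Counts of calls stayed within 1.5 times of the reported ones in all alternatives but those named next, and those without 1 array were 6614 to 7207 for genotype at 12 DAF, 9848 to 9936 at 16 DAF, 10647 to 10946 over both ages, 5280 to 5721 for the interaction, 8676 to 9019 for age in wild type, 6613 to 6895 for age in abi3-6, and 5137 to 5804 shared between ages. With no filter, which adds dim probe sets, the totals of 14477 at 16 DAF and 16262 over both ages were within 1.5 times. Lower calls rose to 9078 (5151 reported) and 10541 (5474), but higher calls only to 5399 (5288) and 5721 (5584). The gain was thus almost all in lower calls. Its cause was not tested, and small reported changes near the dim limit may share it. A fold change of at least 2 as well lowered the counts, in the order above, by construction to 3269, 5929, 4374, 3754, 5065, 3228 and 2394. Welch's test per probe set, which estimates each spread alone, gave 4081 for genotype at 12 DAF, 5903 (2892 higher and 3011 lower, a turned majority) and 4308 for age in wild type and abi3-6, and 2837 shared. With the replicate number as a block the counts were 7555, 10456, 11091, 6002, 9293, 7571 and 5799, and the block changed no call of a list or named gene. Arrays of the same number correlated only between -0.021 and 0.156, and the numbers were not used to pair the samples. Still, 13 of 24 correlated best with their own number (6 of 6 for genotype at 12 DAF, 3 of 6 at 16 DAF), so a pairing stays open. Named genes had 276 values over the contrasts, among them that of BZIP53 at 12 DAF, which did not pass. Of these, 12 lost their call in at least 1 alternative run and 0 turned direction. Named genes and lists were not run with Welch's test or the fold threshold. The stricter filter left 251 of the 276 values, and those it removed were not counted as lost.

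The calls of LEA proteins and light harvesting genes in both genotype contrasts, the interaction and age in wild type held in every alternative run. For LEA proteins and light harvesting genes at 12 DAF the estimated correlation was 0.00377 and -0.0104, under the preset 0.01. Their adjusted p still rose from 3.49e-11 to 0.000383 and from 2.17e-06 to 0.00211 (limma camera, Benjamini-Hochberg). So calls lost with an estimated correlation cannot be put down to members that move together alone, and their cause was not tested. An estimated correlation allows for such members, but was stricter for these lists as well. It left medians as they were and ended these calls, by limma camera and Benjamini-Hochberg adjusted p as given above: chloroplast-encoded genes (0.710 and 0.953 at 12 and 16 DAF), ER body genes (2.65 and 5.68, age in abi3-6 2.26, interaction 1.84), small heat shock proteins (-1.14 and -4.14, age in wild type 3.81), nuclear photosynthesis genes (1.97 at 16 DAF, interaction 0.454), oil and amino acid breakdown at 12 DAF (0.766), oleosins (-2.30 and -6.60, age in abi3-6 -4.35, interaction -3.15), storage proteins (-2.63 at 16 DAF, age in abi3-6 -2.98, interaction -2.51), SWEET transporters (-1.37 and -1.78, interaction -0.597) and expansins (interaction 0.866).

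For the other changes of a list's call the cause was not tested either, apart from the filters, which change which members and probe sets enter. Small heat shock proteins at 12 DAF were lost with array weights (-1.04), no filter (-1.14) and without wild type 12 DAF replicate 2 (-1.12), the range without 1 array being -1.26 to -0.996. Oil and amino acid breakdown at 12 DAF was lost after centring (0.706), with the groups fitted alone (0.766), with the stricter filter (0.663) and without abi3-6 replicate 1 or 2 or wild type replicate 1 or 3 (range without 1 array 0.671 to 0.903, lost ones 0.671 to 0.757). SWEET transporters at 12 DAF were lost after centring (-1.43), quantile normalization (-1.46), with no filter (-0.0645), the stricter filter (-1.33) and without abi3-6 replicate 1 or 2 or wild type replicate 1 (-1.40 to -1.34 where lost, -1.44 to -1.32 over all arrays), and at 16 DAF with no filter (-0.117). Their interaction was lost after centring (-0.673), quantile normalization (-0.556), with no filter (-0.0719) and without abi3-6 12 DAF replicate 1 or 3, abi3-6 16 DAF replicate 3, wild type 12 DAF replicate 3 or wild type 16 DAF replicate 2 or 3 (-0.660 to -0.425 where lost, -0.744 to -0.425 over all arrays). The expansin interaction was lost with no filter (0.0602), and that of nuclear photosynthesis genes without abi3-6 12 DAF replicate 1 (0.435, range 0.341 to 0.638). Passing only in an alternative were expansins at 16 DAF after centring (1.68), quantile normalization (1.6) and without abi3-6 16 DAF replicate 1 or 2 (2.003 and 2.004, range 1.46 to 2.11), acetyl-CoA supply at 16 DAF with no filter (0.492), storage proteins at 12 DAF fitted alone (-0.975), and light harvesting genes for age in abi3-6 with array weights (-0.530), fitted alone (-0.503) and no filter (-0.503). Signal over background limits what can be said of dim genes: 1143 probe sets at 12 DAF and 1585 at 16 DAF gave only a lower bound, and 400 and 191 lay under 3.16 in both genotypes.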

Other observations

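The gene lists of this part were chosen after the annotation had been read and before any comparison was computed, and the test of developmental stage was chosen before its result was seen.

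Several gene groups changed in both directions. Vacuolar processing enzymes, proteases that mature storage proteins, were lower for 3 of 4 at 12 DAF and 1 did not pass: BETA-VPE fell by 1.36 ± 0.22 (SE), DELTA-VPE by 1.34 ± 0.19 and GAMMA-VPE by 0.95 ± 0.14 (median -1.14, limma camera, Benjamini-Hochberg adjusted p = 0.106). At 16 DAF BETA-VPE fell by 2.63 ± 0.22 and GAMMA-VPE by 0.77 ± 0.14, DELTA-VPE rose by 2.38 ± 0.19 and 1 did not pass (median -0.29, adjusted p = 0.805). Seed and gibberellin regulators were higher for 3, lower for 4 and not passed for 7 of 14 at 12 DAF (median -0.16, adjusted p = 0.24), and 4, 9 and 1 at 16 DAF (median -0.89, adjusted p = 0.146). AGL67, a MADS-box gene, fell by 2.11 ± 0.16 at 12 DAF and 2.14 ± 0.16 at 16 DAF, AGL18 fell by 1.51 ± 0.11 and BBM fell by 1.40 ± 0.19 at 12 DAF, and at 16 DAF bZIP44 rose by 3.01 ± 0.18, SPT by 2.76 ± 0.18 and the gibberellin receptor GID1A fell by 1.66 ± 0.17.

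Flavonoid and seed coat genes were higher for 5, lower for 2 and not passed for 2 of 9 at 12 DAF (median 0.52, limma camera, Benjamini-Hochberg adjusted p = 0.418), and 5, 1 and 3 at 16 DAF (median 0.61, adjusted p = 0.101). CHI, chalcone isomerase, was at least 3.59-fold higher at 12 DAF, and UGT78D1 rose by 2.63 ± 0.17 (SE) at 16 DAF while UGT78D2 fell by 0.66 ± 0.18. Cold and dehydration genes were higher for 4, lower for 2 and not passed for 2 of 8 (median 0.56, adjusted p = 0.242), then 4, 1 and 3 (median 0.25, adjusted p = 0.419). DI21 rose by 3.04 ± 0.22 and 3.63 ± 0.22, COR27 fell by 2.02 ± 0.46 at 12 DAF and LTI30 by 0.71 ± 0.15 at 16 DAF. Chaperones and co-chaperones were higher for 4, lower for 2 and not passed for 5 of 11 (median 0.09, adjusted p = 0.704), then 5, 4 and 2 (median 0.21, mean -0.12, adjusted p = 0.957, with the test's direction that of the mean). Fes1B was at least 6.85-fold and at least 33.5-fold higher, and Hop3 fell by 1.37 ± 0.15 and 4.32 ± 0.15. Acetyl-CoA and fatty acid supply genes were higher for 3, lower for 3 and not passed for 7 of 13 (median 0.07, adjusted p = 0.706), then 7, 2 and 4 (median 0.49, adjusted p = 0.258). The ATP-citrate lyase gene ACLA-2 rose by 1.36 ± 0.14 at 12 DAF and at least 7.17-fold at 16 DAF, and PDC2 fell by 2.51 ± 0.20 at 16 DAF. Cell division and replication genes were higher for 4, lower for 1 and not passed for 9 of 14 (median 0.14, adjusted p = 0.575), then 3, 5 and 6 (median 0.16, adjusted p = 0.957), with POLA3 up by 1.02 ± 0.21 and 2.24 ± 0.21 (2 of 3 wild-type arrays above the dim limit) and HTB11 down at 16 DAF (-1.10 ± 0.18). Of 3 endosperm and seed size genes IKU1 fell by 0.60 ± 0.21 and 0.64 ± 0.21 and DME rose by 0.80 ± 0.18 at 16 DAF, the IKU1 calls being lost at 12 DAF with no filter and without abi3-6 replicate 1 (-0.55) or 3 (-0.51) or wild type replicate 2 (-0.52) or 3 (-0.56), and at 16 DAF without abi3-6 replicate 1 (-0.52) or wild type replicate 3 (-0.45).

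A hypothesis was that abi3-6 seeds at 12 DAF stood earlier or further on the course that wild-type seeds took from 12 to 16 DAF. Across probe sets the genotype effect at 12 DAF had r = -0.00615 (rho = 0.00467) with the wild-type age effect, which argues against both as a shift shared by all probe sets. Some lists did go the way of an earlier stage: LEA genes were lower for 16 of 18 at 12 DAF (median -3.76) and rose for 14 with age in wild type (2.24), light harvesting genes were higher for 6 of 6 (2.77) and fell for 5 with age (-2.68), and small heat shock proteins were lower for 3 of 6 (-1.14) and rose for 5 with age (3.81), where both calls of the last list were lost with an estimated correlation (limma camera, Benjamini-Hochberg adjusted p = 0.246 and 0.0574 with an estimated correlation). Other lists went the way of a later stage. Fatty acid breakdown genes were higher for 3 of 3 (1.31) and rose for 3 with age (1.52). Oil and amino acid breakdown genes were higher for 7 of 11 (0.766, limma camera, Benjamini-Hochberg adjusted p = 0.437 with an estimated correlation) and rose for 7 with age (0.734). This list holds the same 3 fatty acid breakdown genes, so it is no separate support. Vacuolar processing enzymes were lower for 3 of 4 (-1.14) and fell for 3 with age (-2.39), though neither shift of that list passed, nor did the age shift of oil and amino acid breakdown genes (adjusted p = 0.258). An earlier or later stage of single groups of genes stays open. The contrasts share wild-type arrays, which alone gave r = 0.499 in 50 simulations of unchanged groups; the covariance was -0.00921 against 0.0225 simulated.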
